A study of Mus musculus with 6 samples.

How the data were processed

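Small RNA was sequenced from NIH 3T3 cells, an immortalised mouse embryo fibroblast line, that had been transfected with a plasmid encoding NXF3 fused to EGFP. Per the labels, 3 input libraries (no antibody) and 3 NXF3 pulldown libraries (anti-GFP antibody on protein A beads) came from 3 separate experiments. The libraries were made with a small RNA kit, amplified with 14 PCR cycles, and products of 30 to 375 nucleotides were cut from a gel, per the labels' protocols. Reads of longer RNAs, mRNAs among them, can therefore come only from fragments and do not measure the intact RNA. Neither a control immunoprecipitation without the bait nor spike-in RNA was used here, so every comparison is of the composition of pulldown RNA against that of input RNA.

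The files hold 1 count table per library, and the values are raw read counts per gene symbol as the authors deposited them. Bowtie and Partek with mouse genome build mm9 are named in the submitters' processing notes. The file names and the summary lines at the end of each table show that rRNA reads had been removed and that reads were counted with HTSeq-count. The versions, the counting mode, the strand setting and the gene annotation are not given in the sources used here. Each table lists 23420 genes, of which 12025 had a read in at least 1 library. The 5 summary lines of the counter name no gene and were left out of library sizes and tests. Of all reads in the tables, 22.2% to 35.6% per library were assigned to a gene, 16.9% to 28.0% fell outside annotated features, 0.197% to 0.427% were ambiguous between genes, 6.75% to 9.18% had a low mapping quality and 27.5% to 51.7% were not aligned. The low-quality share was 9.06% ± 0.106 in input and 8.02% ± 1.14 in the pulldown, lower in every pulldown library than in every input library (exact two-sided permutation p = 0.1, n = 3 each); the other shares overlapped between the groups. The line for reads with several alignments was 0 in every table, and how reads shared by near-identical genes were placed is not given in the sources used here.

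Gene counts totalled 3828642, 1884117 and 3935088 in inputs 1 to 3, and 769570, 6946284 and 3277335 in pulldowns 1 to 3. A count of 0 allows up to 3 counts, or 4.32e-05% to 0.00039% of a library. Such floors and the exact Clopper-Pearson 95% intervals cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. No library pair had identical values, and every pair differed by far more than sampling noise.

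The main test was edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter at its default minimum count of 10, and the quasi-likelihood F test of pulldown against input over all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 1852 genes. TMM factors ran from 0.609 in pulldown 2 to 1.95 in pulldown 1. The 10 most abundant genes of a library took 83.4% to 86.3% of its counts. Standard errors (SE) and 95% intervals of log2 folds were derived from the F statistic and its degrees of freedom. CPM values are library-size-scaled counts after TMM. Gene lists were tested against the other tested genes with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, for lists of at least 3 tested genes. Of 23 lists, 14 could be tested, and their p-values were adjusted together. The fry test was run beside it. A list score per library, the mean log2 CPM of its members minus that of all other tested genes, was compared with an exact two-sided permutation test, as were shares of counts. With 3 libraries against 3 such a test cannot go below 0.1. The labels speak of separate experiments but do not say that equal numbers mark one experiment, so no block for the experiment was used in the main test.

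The lists, the designs, the alternatives and the rule for named genes were fixed before the data were examined. Besides box C/D and box H/ACA snoRNAs, the lists were small Cajal body RNAs, spliceosomal and U7 snRNAs, other stable noncoding RNAs, rRNA genes, microRNA precursors, snoRNA host genes, 5 subsets of snoRNAs (of Rpl13a introns, of Gas5 and Snhg1 introns, for pre-rRNA processing, of the brain-expressed Snrpn region, of the Dlk1-Dio3 region), snoRNP protein genes, nuclear export factor genes, ribosomal protein genes, replication-dependent histone genes, mitochondrially encoded genes, nuclear lncRNAs, and markers of fibroblasts, adipocytes, epithelial cells and leukocytes. Rnu73b, an older name of the form used for a snoRNA, had been put into both the stable RNA and the snRNA list. The rule named, among genes with a mean of at least 10 counts, the 8 largest log2 folds per direction among called genes with the same sign in every same-numbered pair (or the 4 with the smallest p where fewer than 4 were called), the 3 members with the smallest p in each small RNA list and in each other list that passed, and a fixed set that included Nxf3, the Rpl13a intron snoRNAs, Gas5, Snhg1, Rmrp, Rpph1, Terc, Rpl13a and Malat1.

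On data simulated 10 times for this comparison from the real means, dispersions and library sizes, with 200 changed genes among 1475 to 1944 tested, the edgeR test recovered 26.4% of 2-fold, 89.7% of 4-fold and 99.7% of 8-fold changes, and 4.93% of its calls were false. A 2-fold shift of the whole C/D list was called by camera in 10 of 10 runs, and no shift in 0 of 10. Those runs drew genes independently, whereas the estimated inter-gene correlation of the real C/D list was 0.697. The camera rates of the simulation therefore do not carry over to the real lists. The adjusted threshold is also stricter where fewer genes change, and the real comparison called 1 gene. The shares recovered by edgeR in the simulation may therefore be too high for the real data. Alternatives were DESeq2 1.42.0 size factors and its Wald test, total-count scaling, TMM on genes outside the small RNA lists, no filter, a mean of at least 50 counts, limma-voom, a replicate block, an estimated inter-gene correlation, ranks, and leaving out each library. Gene models and transcript lengths of GENCODE M21 and names and biotypes of the RefSeq table for GRCm38.p6 were used for names, lengths and which genes overlap. They belong to another build than mm9, so no coordinates are given. Of the 23420 symbols, 21571 matched a current symbol of the RefSeq table.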

Results

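Small RNA libraries of transfected NIH 3T3 fibroblasts were compared, 3 of input RNA and 3 of RNA recovered with anti-GFP antibody from cells expressing GFP-tagged NXF3, a member of the nuclear export factor family. The title of the series places the question in the localisation of small nucleolar RNAs (snoRNAs), which guide the modification and cleavage of ribosomal RNA in the nucleolus. Gene counts ranged from 769570 in pulldown 1 to 6946284 in pulldown 2. The transcript of the bait gene, Nxf3, was abundant in every library, at 790 ± 329 CPM in input and 1140 ± 380 CPM in the pulldown (SD, n = 3 each). Its log2 fold was 0.53 (SE 0.55, adjusted p = 0.97, edgeR). A read count of this gene reflects RNA, plasmid-derived RNA included if the insert is mouse, and does not measure how much NXF3 protein was recovered.

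Box C/D snoRNAs dominated both kinds of library. The 74 listed C/D snoRNAs, guides of ribose methylation, took 77.6% ± 4.72 of gene counts in input and 75.9% ± 5.64 in the pulldown (SD, n = 3 each). The most abundant genes, picked for their totals after the data were seen, were Gas5 with 16.6% ± 4.89 of input and 19.0% ± 3.20 of pulldown counts, Snord12 with 14.2% ± 3.91 and 14.1% ± 3.60, and Snord55 with 14.8% ± 1.52 and 13.3% ± 0.62. Gas5 is a noncoding gene whose introns hold snoRNAs, and of the 10 such snoRNAs in the fixed list only Snord47 was counted here under its own symbol. How far the Gas5 count holds reads of intronic snoRNAs is uncertain. The 36 box H/ACA snoRNAs, guides of pseudouridylation, took 0.535% ± 0.156 of input and 0.556% ± 0.287 of pulldown counts. The ribosomal precursor Rn45s took 2.63% ± 0.50 of input and 1.59% ± 0.57 of pulldown counts. 

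Both snoRNA classes together made up 78.1% ± 4.78 of input and 76.4% ± 5.39 of pulldown counts. The difference of -1.66 percentage points was smaller than the spread between libraries (exact two-sided permutation test, p = 0.6, n = 3 each, smallest possible p 0.1). Single libraries ran from 70.5% to 82.4%, with exact 95% intervals of at most 0.10 points on either side. Without pulldown 1 the difference was 1.31 points, without input 3 it was 0.49, and with Gas5 counted among the snoRNAs it was 0.66, so its sign rested on these choices. These shares had little room to rise, since snoRNAs and Gas5 together already took 94.7% ± 0.85 of input counts. A moderate enrichment of all of them could stay within the spread between libraries.

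**Figure D1:**
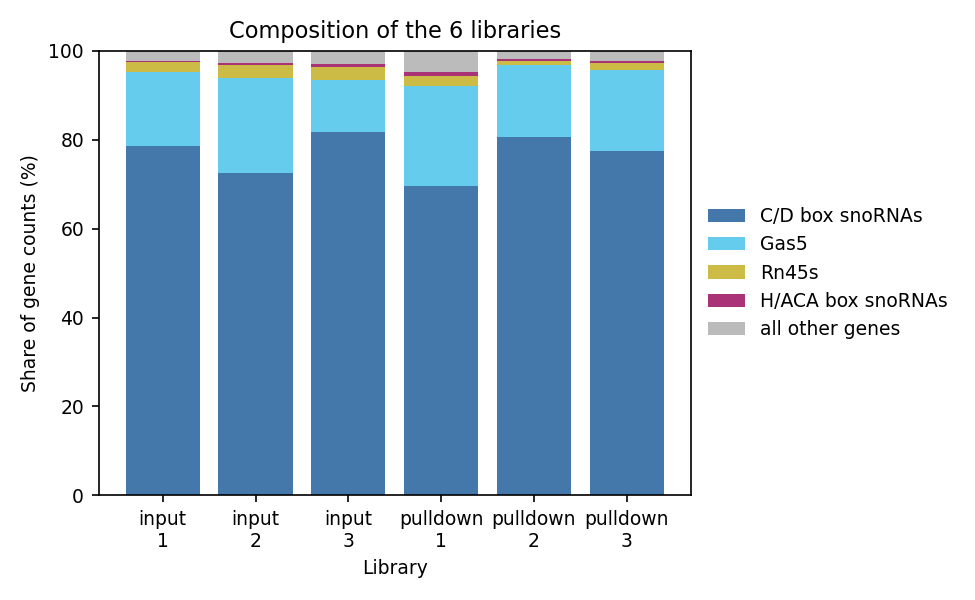
Stacked bars give the share of all gene counts (%, vertical axis) taken by C/D box snoRNAs, Gas5, Rn45s, H/ACA box snoRNAs and all other genes in each of the 6 libraries. C/D snoRNAs fill between 69.6% and 81.7% of every bar, in input and pulldown alike.

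Gene by gene, 1 of 1852 tested genes differed between pulldown and input. 2900060B14Rik, a noncoding gene that lies within Clasp1 on the opposite strand in the GENCODE M21 models, fell from 28.1 ± 7.5 CPM in input to 3.72 ± 2.48 CPM in the pulldown (SD, n = 3 each). Its log2 fold was -2.77 (SE 0.40, 95% interval -3.63 to -1.92, adjusted p = 0.0152, edgeR quasi-likelihood test), a 6.84-fold lower level, and it was lower in 3 of 3 same-numbered pairs. DESeq2 and limma-voom each called this gene and no other lower, total-count scaling ended the call (adjusted p = 0.0846, edgeR), and edgeR without a filter called 9 genes lower. The strand setting of the counting is not given, so reads of Clasp1 cannot be told apart from its own. The 3 genes with the next smallest p among the lower ones did not pass in this test. Hist1h4c, a histone H4 gene, had a log2 fold of -2.06 (SE 0.35, adjusted p = 0.0516, edgeR), Mir15a of -2.69 (SE 0.49, adjusted p = 0.0581, edgeR), and Rnu12, the U12 RNA of the minor spliceosome, of -2.09 (SE 0.46, adjusted p = 0.16, edgeR). Each of these 3 was lower in all 3 pairs.

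No gene passed in the other direction in the main edgeR test or with limma-voom. DESeq2 called 1, Snord33, and so did edgeR restricted to genes with a mean of at least 50 counts (adjusted p = 0.0097), while edgeR without a filter called 7. The 4 higher genes with the smallest p were Snord33, Mir130a, Mir31 and Mir27a. Snord33 had 8.29 ± 1.52 CPM in input and 49.2 ± 35.3 in the pulldown, a log2 fold of 2.60 (SE 0.49, 95% interval 1.55 to 3.64, adjusted p = 0.0581, edgeR), and was higher in 3 of 3 pairs. The log2 folds of the microRNA genes were 1.73 (Mir130a, adjusted p = 0.16), 2.53 (Mir31, adjusted p = 0.304) and 0.96 (Mir27a, adjusted p = 0.36), all by edgeR and all positive in 3 of 3 pairs. At an unadjusted p under 0.05 there were 42 higher and 62 lower genes, 104 in all, where chance alone gives 92.6.

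These counts depended on single pulldown libraries. Pulldown 1 correlated with the other libraries at 0.883 to 0.905 on log2 CPM, against 0.926 to 0.952 for pairs without it. Without pulldown 1, the shallowest, 6 genes were higher (Snord33, Mir31, Mir130a, Mir30a, Mir30d, Mirlet7e) and 5 lower (2900060B14Rik, Rnu12, Hist1h4c, Mir15a, Ctsa); Mir30a, Mir30d, Mirlet7e and Ctsa were named after their values were seen. Without input 2, Mir15a was lower as well. Without pulldown 2 none passed, and the log2 folds were -2.69 for 2900060B14Rik and 1.83 for Snord33 (adjusted p = 0.0796 for both, edgeR).

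**Figure D2:**
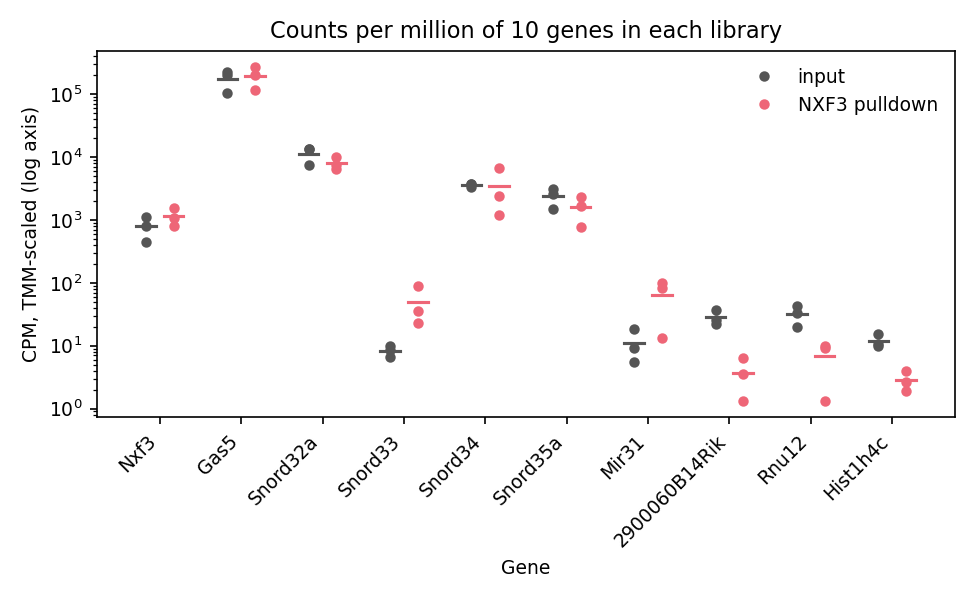
Points give the TMM-scaled CPM (log vertical axis) of 10 genes in each library, grey for input and red for NXF3 pulldown, and short lines the group means. 2900060B14Rik lies lower in all 3 pulldown libraries, and Snord33 lies higher, while Snord32a, Snord34 and Snord35a from introns of the same host gene overlap between the groups.

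Neither snoRNA class was called different from the other genes as a group in the main test. A shift of either list is not excluded, since list scores varied between pulldown libraries (SD 0.98 for C/D and 0.55 for H/ACA, n = 3). Of 62 tested C/D snoRNAs, 0 rose and 0 fell by edgeR, and 34 had positive and 28 negative log2 folds. At an unadjusted p under 0.05, 1 was higher and 0 lower, and adjusted over the list alone 1 was higher, Snord33. The median edgeR log2 fold was 0.07, the mean difference of the list from other genes on log2 CPM was -0.09, and camera gave adjusted p = 0.54. Examples that did not pass were Snord69 (log2 fold 1.11, SE 0.54) and Snord22, the U22 snoRNA (log2 fold -1.04, SE 0.51), both at adjusted p = 0.82 by edgeR. Without pulldown 2 the log2 fold of Snord69 was 0.26, and without pulldown 1 it was 1.55. Of 23 tested H/ACA snoRNAs, 0 rose and 0 fell, over all genes, adjusted over the list alone and at an unadjusted p under 0.05, with a median log2 fold of -0.04, a mean difference of -0.08 and adjusted p = 0.76 by camera. Snora74a had a log2 fold of 0.64 (SE 0.30), Snora62 of 0.77 (SE 0.43) and Snora44 of 0.56 (SE 0.35). The half-width of the unadjusted 95% interval had a median of 1.36 on the log2 scale for single C/D snoRNAs and 0.91 for H/ACA snoRNAs. Smaller changes of many single C/D snoRNAs were therefore not detectable at this spread. Calls adjusted over all 1852 tested genes needed larger changes still. Snord33, at a log2 fold of 2.60, did not pass in the main test.

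The C/D list moved with single libraries. Its score was 7.37 ± 0.34 in input, and 6.28, 8.23 and 7.35 in pulldowns 1 to 3 (difference -0.09, exact permutation p = 1, n = 3 each). Without pulldown 1 its mean difference was 0.42 (camera adjusted p = 2.1e-05), and without pulldown 2 it was -0.58 (camera adjusted p = 4.8e-09). With an estimated correlation these gave adjusted p = 0.68 and adjusted p = 0.51. The H/ACA list reached -0.42 without pulldown 2 (camera adjusted p = 0.00019; adjusted p = 0.3 with an estimated correlation). Within each library, C/D snoRNAs lay above H/ACA snoRNAs by 5.24 ± 0.42 log2 units in input and by 5.23 ± 0.77 in the pulldown, a difference of -0.01 (exact permutation p = 1, n = 3 each).

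The subsets of snoRNAs gave no call over all genes either. Of the 4 snoRNAs in introns of Rpl13a, Snord33 was the one with a positive log2 fold; Snord32a had -0.51 (SE 0.58), Snord34 -0.09 (SE 0.65) and Snord35a -0.61 (SE 0.59), each at adjusted p of 0.97 or above by edgeR. Adjusted over the list alone, 1 was higher, and camera gave adjusted p = 0.95 with a mean difference of 0.20 against a median log2 fold of -0.30. Snord33 is a minor species of this group, with 8.29 CPM in input against 11305 for Snord32a. Reads of the host gene, Rpl13a, had a log2 fold of 1.01 (SE 0.44, adjusted p = 0.82, edgeR), or 0.41 without pulldown 2. This value rests on few reads, 8, 2 and 14 in inputs 1 to 3 and 6, 31 and 9 in pulldowns 1 to 3. The 4 tested snoRNAs of the Dlk1-Dio3 region had 0 calls (mean difference 0.01 but median log2 fold -0.05, camera adjusted p = 0.95), with log2 folds of 0.45 (AF357426), -0.33 (AF357355) and -0.10 (AF357425). Snord47 (log2 fold 0.16, SE 0.69) and Snord22 were the 2 tested members of the Gas5 and Snhg1 subset, Snord22 the 1 of the pre-rRNA processing subset, and Snord64 (log2 fold 0.43, SE 0.53) the 1 of the Snrpn region. Those lists were too small for a list test. U3, U13, U17 and 7SK were not analysed here, and Snord118, the U8 snoRNA, had 1 read in all 6 libraries together.

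Stable noncoding RNAs other than snoRNAs were lower as a list only by camera at the preset correlation. All 4 tested members had negative log2 folds, and the list lay 0.85 log2 units below the other genes (camera adjusted p = 0.0033; adjusted p = 0.49 with an estimated correlation). None was called over all genes, and adjusted over the list alone 2 were lower, Vaultrc5 and Rpph1. Vaultrc5, a vault RNA, had 36.8 ± 13 CPM in input and 13.7 ± 7.3 in the pulldown (log2 fold -1.36, SE 0.42), and Rpph1, the RNA of RNase P, 36.7 ± 11 and 16.7 ± 0.7 (log2 fold -1.13, SE 0.33). Rmrp, the RNA of RNase MRP, had a log2 fold of -0.44 (SE 0.48), and Rnu73b, a snoRNA-type name that the list took in, of -0.16 (SE 0.61). The list score was 4.1 ± 0.20 in input and 3.25 ± 0.62 in the pulldown (exact permutation p = 0.1, n = 3 each, the smallest possible). Adjusted over the 14 tested lists, this permutation p was 0.7. The score of the ribosomal protein list reached the same exact permutation p of 0.1, with a difference of -0.20. The fry test of a common direction in limma gave an adjusted p of 0.31. Terc, the telomerase RNA, had 10, 16 and 43 counts in input and 1, 9 and 9 in the pulldown and was below the filter of the main test. EdgeR without a filter called it lower, but calls of that setting do not compare directly with the main test. Mir31, for example, went from adjusted p = 0.304 to 6.1e-07 there at log2 folds of 2.53 and 2.54 (edgeR).

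**Figure D3:**
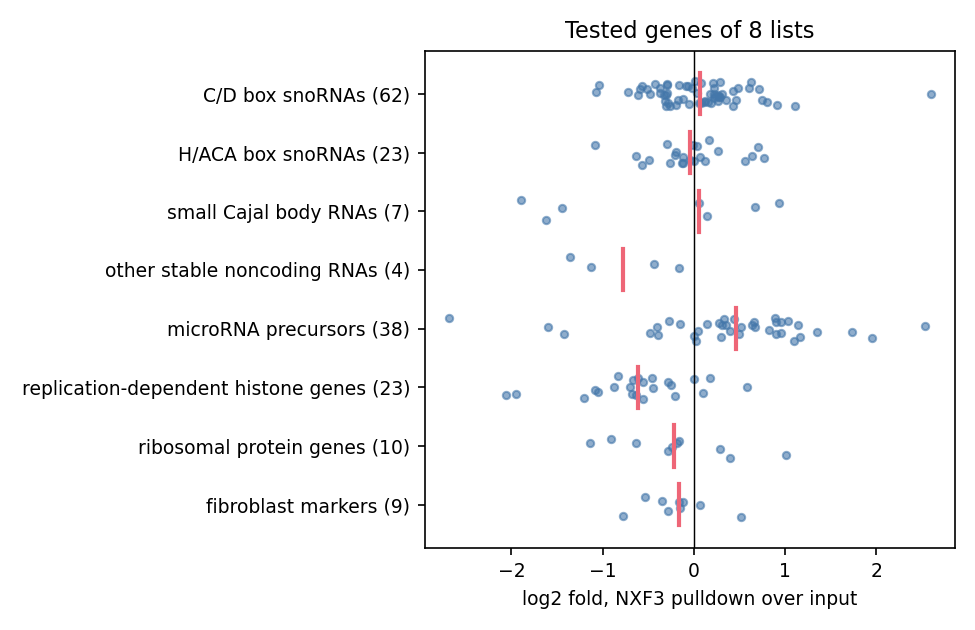
Each point is the log2 fold of 1 tested gene (horizontal axis, NXF3 pulldown over input) in 8 of the gene lists, with the number of tested genes in brackets and a red line at the list's median. Both snoRNA lists centre near 0, while the histone and stable noncoding RNA lists lie to the left.

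Small Cajal body RNAs, which guide the modification of spliceosomal RNAs, had log2 folds of both signs, 4 positive and 3 negative. Of 7 tested, none was called over all genes, and adjusted over the list alone 2 were lower and 1 higher. Scarna13 had a log2 fold of -1.89 (SE 0.47), Scarna8 of -1.62 (SE 0.44) and Scarna17 of 0.93 (SE 0.36). Without input 1, the highest for Scarna13, its log2 fold was -1.14 (adjusted p = 0.89, edgeR), and without pulldown 2 that of Scarna17 was 0.43 (adjusted p = 0.99, edgeR). Camera gave adjusted p = 0.33 for the list, whose mean difference was -0.41 while its median edgeR log2 fold was 0.05. Of the snRNA list only Rnu12 and Rnu73b were tested, and Rnu12 was lower adjusted over the list alone, with 31.9 ± 11.5 CPM in input and 6.76 ± 4.71 in the pulldown. Rn45s, the single tested rRNA gene, had a log2 fold of -0.83 (SE 0.59, adjusted p = 0.95, edgeR) after the rRNA removal.

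MicroRNA genes had mostly positive log2 folds, 30 of 38, with a median of 0.47, but none was called over all genes. Adjusted over the list alone, 3 were higher and 2 lower. The list's mean difference on log2 CPM was -0.01, opposite in sign to its median, and camera placed it upward at adjusted p = 0.91. Its scores in the pulldown were far apart, -1.32, 1.43 and 1.15 in pulldowns 1 to 3, against 0.43 ± 0.37 in input. Without pulldown 1 the mean difference was 0.90 (camera adjusted p = 4.4e-15), and without pulldown 2 it was -0.49 (camera adjusted p = 0.018). With an estimated correlation these gave adjusted p = 0.32 and adjusted p = 0.74. Mir31 illustrates the spread, with 64.9 ± 45.4 CPM in the pulldown and 11 ± 6.7 in input. The files name genes, not mature arms, so no arm is reported.

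Replication-dependent histone mRNAs, which end in a stem-loop instead of a poly(A) tail, were lower as a list only by camera at the preset correlation. Of 23 tested genes, 19 had negative and 4 positive log2 folds, with a median of -0.61. The list lay 0.66 log2 units below other genes (camera adjusted p = 3.4e-07; adjusted p = 0.49 with an estimated correlation). The fry test of a common direction gave an adjusted p of 0.37. No member was called over all genes, and adjusted over the list alone 2 were lower, Hist1h4c and Hist1h3h. Hist1h4c had 12 ± 3.0 CPM in input and 2.84 ± 1.05 in the pulldown, Hist1h3h had a log2 fold of -1.96 (SE 0.45), and Hist3h2a of -1.08 (SE 0.39). The list score was 0.45 ± 0.23 in input and -0.21 ± 0.58 in the pulldown, and pulldown 3, at 0.35, lay inside the input range (exact permutation p = 0.2, n = 3 each). The mean difference was -0.41 without pulldown 1 (camera adjusted p = 0.00022) and -0.997 without pulldown 3 (camera adjusted p = 5.4e-16), with adjusted p = 0.57 and adjusted p = 0.43 at an estimated correlation. Copies of histone genes are near-identical, so single members are uncertain.

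The remaining mRNA and long noncoding RNA lists did not pass. Of 6 tested snoRNA host genes, none was called over all genes and Snhg1, host of U22 and several C/D snoRNAs, was higher adjusted over the list alone (log2 fold 1.18, SE 0.36; camera adjusted p = 0.76 for the list, mean difference 0.13 but median log2 fold -0.11). Gas5 itself had a log2 fold of 0.14 (SE 0.70). Camera gave adjusted p = 0.3 for the 7 nuclear export factor genes and for the 10 ribosomal protein genes (mean differences -0.20 for both; adjusted over the list alone, 0 and 1 lower), 0.91 for the 3 snoRNP protein genes (mean difference 0.06 but median log2 fold -0.15) and the 4 nuclear lncRNAs (mean difference 0.06), and 0.29 for the 9 fibroblast markers (mean difference -0.20). Malat1, a nuclear lncRNA, had a log2 fold of 0.37 (SE 0.50). Markers of other cell types had few reads: none of the adipocyte, epithelial or leukocyte markers had enough counts to test, adipocyte markers reached 0.000356% of a library at most (exact 95% interval 0.000195% to 0.000597%), and no epithelial marker had a read in any library. Mitochondrially encoded genes were not analysed here. The labels give no day or sequencing run for the 6 libraries, so no comparison within such batches was made.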

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

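The alternatives without Rnu73b, with Gas5 among the snoRNAs, with snoRNAs taken by RefSeq biotype, and with an estimated correlation while leaving out single libraries were chosen after seeing the data; the others were planned. The count of lower genes (1) became 0 with total-count scaling and with a mean of at least 50 counts (where 2900060B14Rik is not tested), 2 with TMM outside the small RNA lists, 9 without a filter (with Hist1h3h, Hist1h4c, Mir15a, Rnu12, Scarna13, Scarna3a, Scarna8 and Terc) and 3 with the replicate block (with Hist1h4c and Rnu12, adjusted p = 0.0451 and 0.0167, edgeR); leaving out single libraries gave 0 to 5. The count of higher genes (0) became 7 without a filter and 1 with at least 50 counts, the block or DESeq2 (Snord33 in each), and 0 to 6 without single libraries, the 6 coming without pulldown 1. With total-count scaling 2900060B14Rik had a log2 fold of -2.93 (adjusted p = 0.085, edgeR). To check the pairing, libraries of the 2 groups were correlated on log2 CPM after each gene's group mean was subtracted. None of these correlations between same-numbered libraries exceeded 0.14 (0.03, 0.07 and 0.14 for numbers 1 to 3). The numbers are thus not shown to pair them, although each library correlated best with its own number. Without that subtraction, same-numbered libraries correlated at 0.905, 0.943 and 0.946. The replicate block otherwise changed no list call. The count of called lists (2) became 3 without a filter. It became 0 by camera with an estimated correlation, at adjusted p = 0.49 for the stable RNA and histone lists. This setting cannot move their mean differences of -0.85 and -0.66. Without single libraries the count was 2 to 6, or 0 in each case with an estimated correlation. Values near 0 changed sign. The H/ACA list gave 0.075 with at least 50 counts. The C/D minus H/ACA difference gave 0.00079 with a prior count of 0.5. The snoRNA share difference gave 0.66 with Gas5. The microRNA list gave 0.00027 (TMM outside small RNAs), 0.11 (no filter), 0.198 (at least 50 counts) and 0.196 (limma-voom). The Dlk1-Dio3 list gave -0.033 (no filter) and -0.12 (limma-voom), and without a filter the host gene list gave -0.088 and the export factor list 0.011. Snord47 gave -0.023 (total count), -0.11 (block) and -0.24 (limma-voom), AF357355 gave 0.017 (total count) and AF357426 -0.10 (limma-voom). Without single libraries the ranges were -0.58 to 0.42 for the C/D list, -0.42 to 0.11 for H/ACA, -1.21 to -0.63 for stable RNAs, -0.997 to -0.41 for histones, -0.49 to 0.90 for microRNAs, -0.46 to 0.50 for Dlk1-Dio3, -0.072 to 0.24 for host genes, -0.23 to 0.58 for the Rpl13a subset, -0.17 to 0.40 for snoRNP genes and -0.018 to 0.12 for nuclear lncRNAs. They were -4.23 to 1.31 points for the snoRNA share and -0.23 to 0.44 for C/D minus H/ACA. For single genes they were -0.71 to 0.57 (AF357355), -0.44 to 0.18 (AF357425), -0.69 to 1.29 (AF357426), -0.18 to 0.41 (Gas5), -0.84 to 0.30 (Rnu73b), -1.02 to 0.33 (Snord34), -0.43 to 0.61 (Snord47) and -0.71 to 1.10 (Snord64). Beyond fewer or more genes tested under a filter, the cause was not tested. The 3 scalings moved the median log2 fold of all genes by at most 0.06.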

Other observations

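The tests of summed histone counts, RNA length, the Snord33 ratio and the sequence of 2900060B14Rik, and the bounds that judged the values without single libraries, were chosen or completed after results bearing on them had been seen. Leaving out each library and the counts over splits of the libraries were planned. The annotated transcript of 2900060B14Rik aligned with human U4atac, an RNA of the minor spliceosome, a query sequence supplied from general knowledge and not from the data, at 91.5% identical bases over 129 aligned positions. Reads of this gene may therefore come from U4atac RNA, a hypothesis that tables without read positions cannot settle.

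The first pattern is the lower list mean of histone mRNAs in the pulldown, which passed only by camera at the preset correlation. Without the shallow pulldown 1 the list lay at -0.41 log2 units, but pulldown 3 lay inside the input range, so an effect of pulldown 1 alone cannot be told apart from a lower level in all. Reads moving between near-identical histone copies cannot be told apart from a real fall. The summed histone counts gave a log2 fold of -0.84 (95% interval -1.94 to 0.26). On TMM-scaled CPM the sum was lower in 3 of 3 same-numbered pairs, but the highest pulldown library lay 11.7 CPM above the lowest input. As a share of counts without TMM, the sum was higher in pulldown 1 (0.0479%) than in input 1 (0.0409%). It was lower in pulldowns 2 and 3 than in inputs 2 and 3. Among the 10 splits of the 6 libraries, another reached a mean difference of 0.77 in size against 0.66 for the real one. A weaker recovery of these mRNAs with the bait than of other RNAs may also contribute and was not tested.

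The second pattern is the low level of stable noncoding RNAs such as Vaultrc5 and Rpph1, which passed as a list only by camera at the preset correlation. Without pulldown 1 the list lay at -0.63, and the scores of pulldowns 2 and 3, 3.72 and 3.47, were below the lowest input at 3.90, which argues against that library alone as the cause. RNA length stays open: among 85 snoRNAs the slope of log2 fold on log2 length was -0.15 (95% interval -0.40 to 0.10), its lower bound predicts -0.68 at 281 nucleotides, and the observed median of -1.13 exceeds this by less than the spread of 0.48 among the 3 RNAs, a margin required only after these values were seen. A difference in association with the bait may also be behind it and was not tested.

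The third pattern is Snord33, which stood apart from the other snoRNAs of Rpl13a introns. The log2 ratio of Snord33 to the mean of the other 3, which no scaling moves, was -9.10 ± 0.48 in input and -6.21 ± 0.28 in the pulldown (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), and the lowest pulldown lay 2.21 above the highest input, which argues against scaling. Without pulldown 2, which had the most Snord33 reads, its log2 fold was 1.83, so that library alone is not the cause either. A selective recovery of Snord33 with the bait may remain as a hypothesis, with reads of a related sequence counted under its symbol as an untested alternative. Snord33 was also the higher gene with the smallest p, and it did not pass in the main test (adjusted p = 0.0581, edgeR). The ratio uses the same counts, so it cannot exclude a chance difference in a gene noticed for its rank.

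With 10 splits no share under 0.05 is possible. For genes, 2 of the 10 splits, the real one included, called at least 1 gene. The other of these called 3 and exchanges pulldown 1 for input 3. For lists, 10 of 10, the real one included, called at least 2 lists, and the highest other called 6. The preset correlation of 0.01 behind these calls lay below the estimates for several lists, 0.697 for C/D and 0.504 for histones among them, and with estimated correlations the real split called 0 lists.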
